A study of Mus musculus with 6 samples.

How the data were processed

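The authors deposited, for each of the 6 libraries, UMI counts per gene and barcode. The unit is the count, a whole number of UMIs per the file headers, which name Cell Ranger 3.1.0, and per the labels the reads were aligned with STAR to mm10. The annotation release and read depth are not given in the sources used here. Every barcode in the matrices has at least 500 UMIs, so cells had been called before. Of 32285 genes, 32158 IDs were matched to GENCODE release M21 for coordinates. The groups are the treatment labels, control and OVA-sensitized, with 3 libraries each.

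Barcodes with fewer than 300 genes or over 15% mitochondrial UMIs were left out (32.8 to 35.9% in controls, 29.9 to 32.2% after OVA). Doublets were scored per library with Scrublet as in scanpy, whose own threshold marked only 0.026 to 0.304% of cells; the highest scores at an expected rate of 0.8% per 1000 barcodes were left out instead, a choice made after this was seen. Of 38206 barcodes, 24481 cells were kept. Counts were scaled per cell and log-transformed, and 2000 variable genes, 40 principal components and 20 shared neighbours went into Leiden clustering at resolution 1.0 (seed 1), which gave 35 clusters.

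Clusters were named from marker lists: a class needed 3 markers raised at least 2-fold over the median cluster in at least 25% of cells, and at least as many markers among the top 10 genes as any other class. Clusters with over 30% doublet scores stayed unnamed. After the clusters were seen, those led by cartilage and tendon genes were also left unnamed: they held 26.7 and 57.1% of unnamed cells in controls and 37.2 and 46.5% after OVA, where unnamed cells were 14.7% and 15.4% of all. Lymphoid and myeloid cells were clustered again and named from finer lists. Class names stand for marker profiles.

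UMIs were summed per class and library, for classes with at least 10 cells in each library, and over all kept cells. Per library the sums held 6882690 to 15235834 UMIs in keratinocyte-like, 4024975 to 7191109 in fibroblast-like, 791310 to 1564793 in vascular, 335764 to 864223 in dendritic, 257614 to 472382 in macrophage- and monocyte-like and 98648 to 212902 in lymphoid cells, and the last limits what can be seen. Genes were kept with edgeR's filterByExpr, scaled by TMM and tested with edgeR's quasi-likelihood test. P-values were adjusted by Benjamini-Hochberg over the genes tested in a comparison, with a threshold of 0.05. Cell numbers per class were tested with edgeR, with library size the number of cells and the spread between libraries shared over the classes. Shares were tested with a two-sided exact permutation test, which cannot go below 0.1 for 3 against 3.

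The 21 gene lists were tested with limma's camera at a preset correlation between genes of 0.01 and, as an alternative, an estimated one, where at least 5 members were tested, adjusted over the lists of a comparison. With the estimated correlation the lists that kept their calls were MHC class II genes in macrophage- and monocyte-like cells, matrix genes in pericyte-like cells, interferon-stimulated genes in vascular cells and barrier genes in vascular and lymphatic cells. Krt85, Scart1, Scart2, Il26, Il36a, Il36b, Il36g, Mx1, Mx2 and Ctgf are list symbols that the gene table lacks. A gene counts as over 10-fold higher in another class when its mean CPM is under a fraction of 0.1 of that in the class with the highest.

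The genes named come from a set fixed by a rule, of which some were left out, for length after their values were seen or because they may not be named: the 8 largest rises and falls (4 in the lymphatic, pericyte, sebocyte, Schwann and hair classes) among genes past the threshold with no overlap between groups and a mean of at least 20 CPM in the higher group, leaving out predicted, ribosomal and mitochondrial genes; up to 4 members past the threshold of each list described, or the 2 with the smallest p; and fixed genes. These are Il4, Il13, Il5, Il17a, Il22, Ifng and Foxp3 in lymphoid cells and all cells; Tslp, Il33, Flg, Lor, Krt6a, Krt16, S100a8 and S100a9 in keratinocyte-like cells and all cells; Ccl11, Ccl8, Postn and Il33 in fibroblast-like, Ccl17, Ccl22 and Ccr7 in dendritic, Retnla, Chil3 and Ccl24 in macrophage-like and Sele, Selp and Vcam1 in vascular cells. Lists, markers, thresholds, tests, this rule and the alternatives but 3 were chosen before the data were examined. The same mix of clusters (only where a class had more than 1), that of second-level clusters and cells named at the second clustering were added afterwards.

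Where a group had 0 UMIs of a gene, the fold is a lower bound against 3 counts over the group, and with 1 to 3 UMIs a ratio is given with its 95% exact interval. Shares of cells carry 95% exact Clopper-Pearson intervals, also after thinning each cell to 1000 UMIs. Intervals and floors cover counting error only.

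The tests were checked on simulated data in which 200 genes were changed: at a log2 fold of 1, 96% were recovered in all cells, 91.9% in keratinocyte-like and 67.8% in lymphoid cells, with 1.52, 3.11 and 5.88% of calls false. Alternatives were DESeq2, its size factors in edgeR, no filter on low counts, each library left out in turn, the replicate number as a block, stricter cells (500 genes, 8% mitochondrial), doublets kept, equal numbers of cells, all barcodes, other cluster resolutions (0.5 and 2.0, and 0.6 for the second clustering), genes over 10-fold higher in another class left out, and other denominators or TMM for cell numbers. Melanocyte-, basophil-, neutrophil-like and muscle cells were too few for gene tests.

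Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.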

Results

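Single-cell transcriptomes were measured in skin of Balb/c mice. The labels describe all 6 libraries, controls included, as sensitized skin taken 2 days after 10 days of sensitization, so the groups rest on the treatment label. The skin was digested with enzymes, and the libraries were made with 10x Genomics 3' chemistry, which counts transcripts as unique molecular identifiers (UMIs). There were 3 control libraries and 3 OVA-sensitized libraries (n = 3 per group throughout). The labels give the cell type of all libraries as CD4, whereas the clusters described here hold keratinocytes, fibroblasts, endothelial cells and leukocytes, so the libraries are treated as whole-skin suspensions. The labels do not say whether replicates were separate mice, so each p-value measures only the spread between these libraries, which may be technical. After filtering, control libraries 1 to 3 held 5004, 4377 and 4120 cells with 28122086, 25509901 and 25096529 UMIs, and OVA-sensitized libraries 1 to 3 held 3670, 3905 and 3405 cells with 22305695, 23019291 and 21743490 UMIs. The median per cell was 4527.5, 4737 and 4922 UMIs in the controls and 5024, 4864 and 5193 after OVA. Unless stated otherwise, a change is the log2 fold of OVA-sensitized over control ± SE from edgeR, and shares and CPM values, counts scaled to a library total of 1e6 UMIs, are means ± SD of 3 libraries. Coordinates are mm10 (GRCm38), counted from 1, from GENCODE release M21.

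The comparison of cell classes asks which cells made up the skin suspension in each group. It rests on kept cells: of barcodes with at least 300 genes, 22.1 to 23.1% in controls and 14.1 to 15.2% after OVA were left out for mitochondrial UMIs, and their classes are not known. Keratinocyte-like cells fell from 39.3 ± 0.441% to 21.8 ± 1.1% of cells (log2 -0.85 ± 0.04, adjusted p = 8.0e-26). Fibroblast-like cells rose from 19.3 ± 0.456% to 27.3 ± 1.67% (log2 0.50 ± 0.05, adjusted p = 5.21e-14). Leukocyte classes rose by more. Dendritic- and Langerhans-like cells rose from 1.89 ± 0.185% to 4.33 ± 0.324% (log2 1.21 ± 0.12, adjusted p = 1.95e-13). Macrophage- and monocyte-like cells rose from 3.73 ± 0.0315% to 7.01 ± 0.426% (log2 0.91 ± 0.09, adjusted p = 2.27e-13) and lymphoid cells from 1.13 ± 0.128% to 2.43 ± 0.0308% (log2 1.09 ± 0.16, adjusted p = 9.74e-09). Basophil-like cells numbered 1 in all control libraries and 45 after OVA (0.405 ± 0.199%, adjusted p = 2.69e-09), and neutrophil-like cells 3 and 64 (0.591 ± 0.183%, adjusted p = 7.67e-11). With stricter cells the share of neutrophil-like cells was 0.0327% after OVA and 0 in controls, too few for a test, while the basophil call was kept (adjusted p = 2.73e-06). Among vessel cells, vascular endothelial-like cells rose from 5.11 ± 0.29% to 6.96 ± 0.134% (log2 0.44 ± 0.09, adjusted p = 7.31e-06). Pericyte- and smooth muscle-like cells rose from 2.88 ± 0.209% to 3.52 ± 0.292% (log2 0.29 ± 0.12, adjusted p = 0.0183), and the value for lymphatic endothelial-like cells was 0.23 ± 0.12 (adjusted p = 0.0627). Hair matrix (log2 -0.40 ± 0.12, adjusted p = 0.00329), Schwann-like (-0.41 ± 0.13, adjusted p = 0.0049), sebocyte-like (-0.45 ± 0.16, adjusted p = 0.00744) and melanocyte-like cells (-0.58 ± 0.26, adjusted p = 0.0371) fell, and the few skeletal muscle cells gave log2 0.62 ± 0.48 (adjusted p = 0.198).

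In each of these classes but melanocyte-like and muscle cells the 3 libraries of one group lay apart from the 3 of the other, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 can give (0.115 adjusted over the classes). Shares depend on one another: among cells other than epithelial ones the log2 values were 0.08 for fibroblast-like, 0.02 for vascular, -0.13 for pericyte-like and -0.19 for lymphatic cells. Among leukocytes they were -0.03 for lymphoid, 0.09 for dendritic and -0.22 for macrophage-like cells (the last with adjusted p = 0.0158, all others above the threshold). Calls were lost for hair matrix cells without control library 2 (adjusted p = 0.058) or OVA-sensitized library 3 (0.051), for sebocyte-like cells without OVA-sensitized library 2 (0.0562), and for pericyte-like cells without control library 1 (0.0584), control library 2 (0.103) or OVA-sensitized library 1 (0.0728). The melanocyte call was lost without control library 1 (0.0917), 2 (0.114) or 3 (0.138) and without OVA-sensitized library 2 (0.426) or 3 (0.0666). Lymphatic cells passed without OVA-sensitized library 1 (0.0489) or 2 (0.0272).

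A second clustering split the lymphoid and myeloid cells. Among lymphoid cells (154 in controls, 267 after OVA), conventional CD4 T-like cells rose from 10.4 ± 3.81% to 22.4 ± 4.73% (log2 1.10 ± 0.32, adjusted p = 0.0134). NK-like cells rose from 4.47 ± 2.04% to 10.8 ± 3.26% (1.23 ± 0.46, adjusted p = 0.0315) and regulatory T-like cells from 8.35 ± 1.71% to 16.4 ± 5.66% (0.92 ± 0.36, adjusted p = 0.0315). Dermal gamma-delta T-like cells fell from 30.5 ± 5.59% to 18 ± 2.13% of lymphoid cells (-0.73 ± 0.25, adjusted p = 0.0291), with 46 such cells in the controls and 48 after OVA. Among myeloid cells (762 and 1354), monocyte-like cells rose from 3.34 ± 1.55% to 17.1 ± 1.73% (log2 2.30 ± 0.26, adjusted p = 7.05e-05), and macrophage-like cells fell from 52.9 ± 0.82% to 34.1 ± 0.988% (-0.63 ± 0.07, adjusted p = 7.05e-05), with 403 and 461 cells. Langerhans-like cells, the resident antigen-presenting cells of the epidermis, fell from 6.45 ± 0.736% to 1.3 ± 0.679% of myeloid cells (-2.24 ± 0.35, adjusted p = 0.000463), with 49 and 18 cells. Keratinocyte-like cells, also of the epidermis, numbered 5307 in controls and 2395 after OVA. Whether Langerhans-like cells fell relative to other epidermal cells was not tested. Conventional dendritic-like cells rose from 4.27 ± 1.77% to 8.54 ± 1.31% of myeloid cells (1.01 ± 0.29, adjusted p = 0.0091). Migratory dendritic-like cells gave 0.62 ± 0.52 (adjusted p = 0.267). With the second clustering at resolution 0.6 the value for conventional dendritic-like cells was -0.08. The monocyte-like cells were led by Thbs1, AW112010, Ly6c2, Plac8 and Irf7 and also raised 83.3% of the macrophage markers. NK calls were lost without control library 1 (adjusted p = 0.0679), 2 (0.0647) or 3 (0.0944) or OVA-sensitized library 1 (0.0871), and regulatory T calls without these (in the same order 0.0679, 0.102, 0.0638 and 0.0774) or OVA-sensitized library 3 (0.155). The CD4 T call was lost without control library 2 (0.0647), the gamma-delta call without control library 2 (0.102) or 3 (0.0638), and migratory dendritic-like cells passed without control library 3 (0.0418).

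The next comparison asks which cells held cytokine transcripts. After OVA, Il4 (ENSMUSG00000000869, chromosome 11, 53602982 to 53618669, minus strand) gave 86 UMIs, of which 78 (90.7%) lay in basophil-like and 6 in lymphoid cells. Il13 (ENSMUSG00000020383, chromosome 11, 53631324 to 53634702, minus strand) gave 392, of which 257 (65.6%) lay in basophil-like and 125 (31.9%) in lymphoid cells. Both drive type 2 immunity. In the controls Il4 gave 0 UMIs and Il13 17, of which 15 lay in lymphoid cells. Il5, the eosinophil growth factor, gave 3 UMIs in controls and 70 after OVA (68 in lymphoid cells), Il17a 12 and 109, Il22 1 and 85 and Ifng 1 and 129, the last 3 all in lymphoid cells. Foxp3, the regulatory T cell factor, gave 5 and 30. Il4 or Il13 was seen in 27 of 45 basophil-like cells after OVA (60.0%, exact Clopper-Pearson 95% interval 44.3 to 74.3, median 1416 UMIs per cell; 57.5% of cells thinned to 1000 UMIs), though the naming of that cluster used Il4 and its top genes include Il13. Among lymphoid cells the share was 5.04 ± 3.93% in the controls and 7.03 ± 2.04% after OVA (exact permutation p = 0.4, two-sided, median 2047.5 and 1908 UMIs per cell), a difference within the spread between libraries. Conventional CD4 T-like cells held 88 of the Il13 UMIs after OVA, in 9 of 60 cells with either transcript, against 0 of 16 in the controls. Unnamed lymphoid cells held 35, in 9 of 87 cells with either, against 12 in 5 of 72 in the controls. Keratinocyte-like cells, taken as background, gave 3 of 2395 cells after OVA (0.125%, median 7650 UMIs) and fibroblast-like cells 3 of 3004 (0.0999%, median 6032.5 UMIs), with 0 of either in the controls (upper limits of detected shares 0.0695% and 0.141%).

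**Figure D1:**
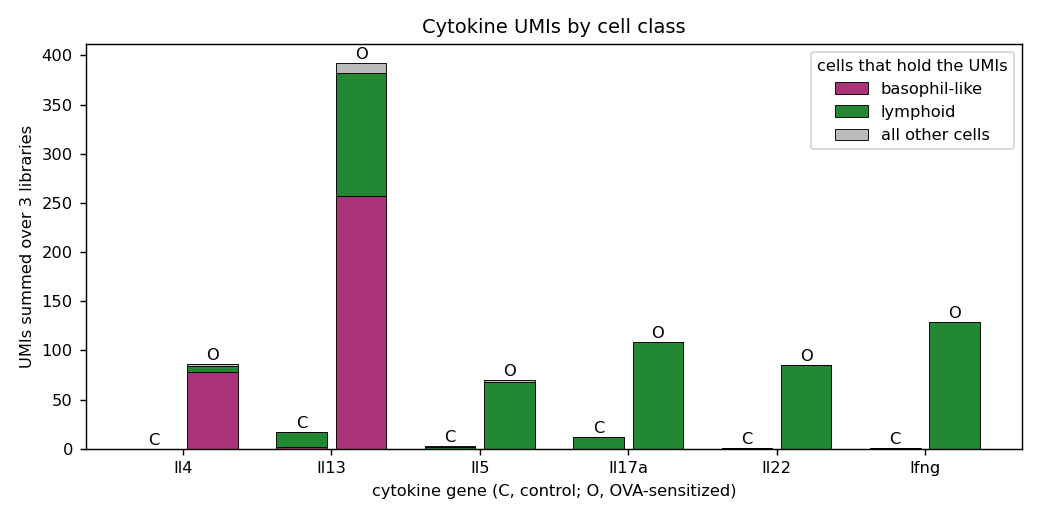
UMIs of Il4, Il13, Il5, Il17a, Il22 and Ifng (y axis, summed over 3 libraries) in control (C) and OVA-sensitized (O) libraries, with bars split into basophil-like, lymphoid and other cells. Il13 reached 392 UMIs after OVA and 17 in controls.

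Summing all kept cells of a library asks how the RNA of the whole suspension differed, which joins changes within cells to the change in their mix. The chemokine Cxcl5 (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624, plus strand), which attracts neutrophils, rose from 8.82 ± 3.82 to 117 ± 7.55 CPM (log2 3.72 ± 0.26, adjusted p = 2.92e-05). The carbonic anhydrase Car4 (ENSMUSG00000000805, chromosome 11, 84957786 to 84966044, plus strand) rose from 0.945 ± 0.0146 to 21.4 ± 5.21 CPM (4.49 ± 0.21, adjusted p = 6.95e-06). Ccl8 (ENSMUSG00000009185, chromosome 11, 82115185 to 82116799, plus strand), a chemokine of macrophages, rose from 78.2 ± 13.4 to 342 ± 70.1 CPM (2.13 ± 0.17, adjusted p = 5.04e-05). Plac8 rose too (2.54 ± 0.13), as did Hdc, Ccl3 and Ccl4 (3.09 ± 0.32, 2.78 ± 0.45 and 2.06 ± 0.36), top genes of the basophil-like cluster, and S100a8 and S100a9 (3.02 ± 0.23 and 3.86 ± 0.32), top genes of the neutrophil-like cluster (adjusted p at most 0.00235). Ccl3 and Ccl4 are close paralogs, and reads shared between them were not resolved. Large falls were in genes of epidermis and hair: Krt71 (-1.67 ± 0.53), Krt24 (-1.65 ± 0.22) and Tgm3 (-1.44 ± 0.06), with adjusted p at most 0.0326. Tslp (ENSMUSG00000024379, chromosome 18, 32815383 to 32819797, plus strand), an epithelial cytokine that activates dendritic cells, fell by 1.03 on the log2 scale (adjusted p = 0.000177). Lor and Krt6a fell (-1.01 ± 0.24 and -0.53 ± 0.12, adjusted p at most 0.00933), as did Krt16 (-0.29 ± 0.07). Il33 and Flg gave -0.01 ± 0.06 and -0.78 ± 0.38 (adjusted p = 0.877 and 0.128). In the sums 3369 genes rose and 3348 fell of 14930 tested, 6639 of them without overlap between groups, as were 56.2% of all tested genes (10% by chance).

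By gene list, matrix and remodelling genes rose together, with 25 of 28 up and 2 down (the same adjusted over the list alone, adjusted p = 3.0e-12, or 0.197 with an estimated correlation). Endothelial adhesion genes rose, with 18 of 19 up and 0 down (the same adjusted over the list alone, adjusted p = 1.53e-08, or 0.197 with an estimated correlation). Interferon-gamma induced and MHC class II genes, which serve antigen presentation, rose, with 20 of 22 up and 1 down (the same adjusted over the list alone, adjusted p = 1.41e-08, or 0.197 with an estimated correlation). Interferon-stimulated genes rose, with 11 of 24 up and 0 down (12 and 0 adjusted over the list alone, adjusted p = 0.000391, or 0.197 with an estimated correlation). Chemokine genes rose, with 19 of 29 up and 2 down (20 and 2 adjusted over the list alone, adjusted p = 8.08e-05, or 0.284 with an estimated correlation), Cxcl3 by 3.12 ± 0.22. Genes of the response to IL-4 and IL-13 rose, with 15 of 22 up and 2 down (15 and 3 adjusted over the list alone, adjusted p = 0.000391, or 0.243 with an estimated correlation). Itch and neuro-immune mediators rose, with 9 of 20 up and 3 down (the same adjusted over the list alone, adjusted p = 0.0298, or 0.197 with an estimated correlation). The cytotoxic list rose, with 4 of 6 up and 0 down (the same adjusted over the list alone, adjusted p = 0.035, or 0.406 with an estimated correlation), a call lost without OVA-sensitized library 2 (adjusted p = 0.108). Gzma (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981, minus strand), a granule protease of killer cells, went from 0 to 201 UMIs, at least 78.6-fold higher against a floor of 3 counts over the control group.

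Barrier and cornification genes fell, with 1 of 25 up and 16 down (the same adjusted over the list alone, adjusted p = 8.08e-05, or 0.197 with an estimated correlation). Epidermal lipid and ceramide genes fell, with 2 of 29 up and 16 down (2 and 17 adjusted over the list alone, adjusted p = 0.00045, or 0.406 with an estimated correlation). The share of keratinocyte-like cells fell in the same libraries. Cell cycle genes fell, with 0 of 25 up and 10 down (0 and 9 adjusted over the list alone, adjusted p = 0.011, or 0.55 with an estimated correlation). Genes raised by tissue dissociation fell, with 4 of 24 up and 12 down (the same adjusted over the list alone, adjusted p = 0.0233, or 0.406 with an estimated correlation). The remaining lists did not pass. Type 2 cytokines and their cells had 4 of 8 up and 1 down (4 and 2 adjusted over the list alone, adjusted p = 0.372), with Il13 (4.67 ± 0.81) up and Gata3 (-0.79 ± 0.06) down. The IL-17 and IL-22 axis had 2 of 5 up and 2 down (the same adjusted over the list alone, adjusted p = 0.784). Regulatory T cell genes had 3 of 7 up and 1 down (the same adjusted over the list alone, adjusted p = 0.407). Alarmins and the IL-1 family had 2 of 10 up and 2 down (the same adjusted over the list alone, adjusted p = 0.793). Keratinocyte stress genes had 4 of 23 up and 8 down (the same adjusted over the list alone, adjusted p = 0.372). Glycolysis and hypoxia genes had 5 of 21 up and 5 down (6 and 6 adjusted over the list alone, adjusted p = 0.767). Blood cell RNA had 0 of 5 up and 1 down (the same adjusted over the list alone, adjusted p = 0.372), with Alas2 (-1.30 ± 0.35) down, which turned to 0.47 with doublets kept (adjusted p = 0.714). Skeletal muscle RNA had 1 of 8 up and 0 down (0 and 0 adjusted over the list alone, adjusted p = 0.415). Of the sex-linked list only Xist (-0.15 ± 0.14, adjusted p = 0.414) and Tsix (0.07 ± 0.31, adjusted p = 0.879) were tested, too few for a list test. Median, mean and test differed in sign for the IL-17 axis (median 0.31, mean -0.04, test up), alarmins (-0.02, 0.01, up), keratinocyte stress (-0.29, 0.13, down) and glycolysis (-0.05, 0.07, down). In DESeq2, Krt71, Alas2 and Pvalb were not called. Calls lost by leaving out 1 library numbered 7 without control library 1 (adjusted p 0.0761 to 0.159), 6 without 2 (0.0506 to 0.128) and 7 without 3 (0.0555 to 0.125). Losses were 9 without OVA-sensitized library 1 (adjusted p 0.0626 to 0.159), 5 without 2 (0.0505 to 0.194) and 3 without 3 (0.0705 to 0.137). The genes were Il1rn, Hrnr, Lce3c, Sprr2k, Ccnb1, Bnip3, Pvalb, Nkg7, Alas2 and Krt71.

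Within keratinocyte-like cells the question is which epidermal genes changed. Il24 (ENSMUSG00000026420, chromosome 1, 130882074 to 130887454, minus strand), a cytokine of the IL-10 family, rose from 7.77 ± 0.45 to 19.4 ± 0.938 CPM (log2 1.31 ± 0.09, adjusted p = 0.00076). Tslp fell from 54 ± 4.12 to 31.8 ± 8.37 CPM (-0.76 ± 0.14, adjusted p = 0.0205). Rises were seen in Sprr2a3 (1.32 ± 0.15), Akr1c18 (1.02 ± 0.12), Defb6 (0.94 ± 0.20), Alox12e (0.86 ± 0.14) and Slc7a8 (0.80 ± 0.08), where Sprr2a3 belongs to a family of near-identical genes, Defb6 is an antimicrobial peptide and Alox12e an epidermal lipoxygenase (adjusted p at most 0.0329). Falls were seen in Krt24 (-0.84 ± 0.19), Tgm3 (-0.65 ± 0.06) and Ly6a (-0.64 ± 0.07), with adjusted p at most 0.0482. H2-Aa, Col1a1 and Tnc also rose (1.43 ± 0.33, 0.87 ± 0.18 and 0.84 ± 0.08), though all 3, like Ly6a, were over 10-fold higher in another class. In this class 259 genes rose and 119 fell of 11719 tested, 378 of them without overlap between groups, as were 25.2% of all tested genes (10% by chance).

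Keratinocyte stress genes rose, with 8 of 20 up and 0 down (12 and 0 adjusted over the list alone, adjusted p = 2.34e-07, or 0.161 with an estimated correlation). Rises were Lce3c (1.85 ± 0.30), Krt6b (1.62 ± 0.36), Slpi (0.71 ± 0.09) and Krt16 (0.47 ± 0.08), keratin 16 being a marker of wounded or inflamed epidermis. Krt6a gave 0.27 ± 0.12 (adjusted p = 0.261). S100a8 and S100a9 gave 5 and 33 and 59 and 37 UMIs, and S100a9 a value of 0.32 ± 0.48 (adjusted p = 0.783). Of 9 alarmin and IL-1 family genes 1 rose and 1 fell (4 and 1 adjusted over the list alone). As a list they passed upward (adjusted p = 0.0463, or 0.287 with an estimated correlation). The call was lost without control library 1 (0.0516), 2 (0.0502) or 3 (0.064) or OVA-sensitized library 1 (0.0835) or 3 (0.195). Il33 gave 0.27 ± 0.08 (adjusted p = 0.104), and Tslp fell. Chemokine genes rose, with 7 of 15 up and 0 down (9 and 0 adjusted over the list alone, adjusted p = 0.000178, or 0.0827 with an estimated correlation). Of these, Ccl4 (2.35 ± 0.40), Ccl8 (2.16 ± 0.29), Ccl7 (0.74 ± 0.10) and Cxcl12 (0.60 ± 0.08) were each over 10-fold higher in another class. Barrier genes had 2 of 24 up and 1 down (6 and 1 adjusted over the list alone, adjusted p = 0.0946), with Asprv1 (0.65 ± 0.09), a protease that processes filaggrin, and Cldn1 (0.28 ± 0.06) up. Flg and Lor gave 0.09 ± 0.37 and -0.25 ± 0.25 (adjusted p = 0.93 and 0.657). Lipid genes had 0 of 28 up and 1 down (2 and 1 adjusted over the list alone, adjusted p = 0.106). Interferon-stimulated genes had 0 of 13 up and 1 down (the same adjusted over the list alone, adjusted p = 0.447), with Ifi27l2a (-0.55 ± 0.10) down and over 10-fold higher elsewhere. Cell cycle genes had 0 of 25 up and 0 down (the same adjusted over the list alone, adjusted p = 0.687). Dissociation genes had 1 of 24 up and 3 down (the same adjusted over the list alone, adjusted p = 0.572). The median was -0.00381, the mean 0.00171 and the test pointed down. The mix of clusters differed: the Krt5 and Krt14 cluster held 26.9% of the class in controls and 15.5% after OVA, the Gjb2 and Krt17 cluster 11% and 17.5% and the Akr1c18 cluster 16.5% and 22.7%. Given the same number of cells per cluster from every library 39 genes passed, 29 of them among the 378, and 11 of 32 named calls were kept, those of Il24, Sprr2a3, Lce3c, Krt16 and Asprv1 among them. The chemokine call was lost there (median 0.07, adjusted p = 0.232, against 0.32 in the whole class), and the barrier list rose (adjusted p = 0.00269). The count was 109, 97 and 84 without control libraries 1, 2 and 3 and 187 without OVA-sensitized library 1. Named calls lost by leaving out 1 library were 14 without control library 1 (adjusted p 0.0546 to 0.165), 15 without 2 (0.051 to 0.168) and 15 without 3 (0.0673 to 0.169). Losses were 9 without OVA-sensitized library 1 (adjusted p 0.0521 to 0.133), 4 without 2 (0.0573 to 0.0992) and 8 without 3 (0.056 to 0.119). The genes were H2-Aa, Defb6, Alox12e, Krt24, Tslp, Ier2, Ier3, Jun, Cldn1, Lce3c, Hmgcs1, Ccl4, Ifi27l2a, Krt16, Col1a1 and Krt6b.

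In fibroblast-like cells, Cxcl5 rose from 26.8 ± 15.9 to 363 ± 36.8 CPM (log2 3.76 ± 0.27, adjusted p = 3.41e-06). Il33, an alarmin that activates type 2 lymphocytes, rose from 19.3 ± 1.38 to 36.2 ± 4.57 CPM (0.91 ± 0.12, adjusted p = 0.000313) and the matrix protein gene Tnc from 171 ± 11.3 to 444 ± 37.4 CPM (1.38 ± 0.08, adjusted p = 1.06e-06). Other large rises were Reg3g (5.66 ± 1.15), Tnn (2.56 ± 0.14), Egfl6 (2.41 ± 0.15), Spp1 (2.31 ± 0.22), Ccnb2 (2.24 ± 0.15), Cdca3 (2.07 ± 0.17) and Ube2c (2.01 ± 0.21), with adjusted p at most 0.00864. Reg3g encodes an antimicrobial lectin, and Ccnb2, Cdca3 and Ube2c act in mitosis. The largest fall was in Wrap53 (ENSMUSG00000041346, chromosome 11, 69561758 to 69580255, minus strand; -2.56 ± 0.21, adjusted p = 1.57e-05). Other large falls were in epidermal genes: Krt2 (-2.14 ± 0.17), Gsta3 (-2.05 ± 0.20), Ly6d (-1.95 ± 0.10) and Krtdap (-1.90 ± 0.17), each over 10-fold higher in another class. Keratinocyte markers summed to 1924 CPM in control and 738 CPM in OVA-sensitized fibroblast-like cells, and 20 of 23 fell. Here 565 genes rose and 420 fell of 11399 tested, 983 of them without overlap between groups, as were 27% of all tested genes (10% by chance).

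Matrix genes rose, with 17 of 28 up and 1 down (20 and 1 adjusted over the list alone, adjusted p = 6.62e-12, or 0.0651 with an estimated correlation). Col12a1, Lox and Timp1 rose (1.11 ± 0.07, 0.98 ± 0.07 and 0.97 ± 0.07), Lox being the enzyme that crosslinks collagen. Chemokine genes rose, with 7 of 20 up and 1 down (the same adjusted over the list alone, adjusted p = 0.000853, or 0.0827 with an estimated correlation). Rises were Cxcl3 (3.90 ± 0.37), Cxcl9 (3.20 ± 0.61) and Ccl5 (2.32 ± 0.37), of which Cxcl3 and Ccl5 were over 10-fold higher in another class. Ccl11 gave 0.44 ± 0.17 (adjusted p = 0.154). IL-4 and IL-13 response genes rose, with 2 of 9 up and 0 down (the same adjusted over the list alone, adjusted p = 0.00128, or 0.118 with an estimated correlation). The members were Postn (0.48 ± 0.06), a matrix protein of allergic tissue, and Ccl8 (1.20 ± 0.13), which was over 10-fold higher in another class. Interferon-stimulated genes had 2 of 19 up and 3 down (4 and 4 adjusted over the list alone, adjusted p = 0.682). The median was -0.13, the mean 0.01 and the test pointed down. Dissociation genes fell, with 2 of 24 up and 10 down (2 and 14 adjusted over the list alone, adjusted p = 7.98e-06, or 0.091 with an estimated correlation). A cluster led by Il1rl1, Cthrc1, Cxcl5 and Tnn held 0.147% of the class in controls and 7.08% after OVA, and 27.1% of its cells had high doublet scores. On the same mix of clusters 377 genes passed, 367 of them among the 985, and 27 of 34 named calls were kept. The count was 615 and 647 without control libraries 1 and 3. Leaving out 1 library cost named calls, namely 3 without control library 1 (adjusted p 0.0551 to 0.126), 3 without 2 (0.0628 to 0.096) and 3 without 3 (0.0534 to 0.118). Losses were 2 without OVA-sensitized library 1 (adjusted p 0.0692 to 0.103), 4 without 2 (0.0593 to 0.0655) and 1 without 3 (0.0504). The genes were Hspa1b, Ifi27l2a, Irf7, Stat2 and Reg3g.

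In lymphoid cells, Gzma went from 0 to 195 UMIs, at least 36.6-fold higher (adjusted p = 0.000552). Ccl5, a chemokine of activated T cells, rose from 29.7 ± 17.8 to 799.6 ± 448 CPM (log2 4.71 ± 0.56, adjusted p = 0.000206). Ctla4, an inhibitory receptor of activated and regulatory T cells, rose (2.16 ± 0.33, adjusted p = 0.00149). So did Il1r2 (3.1 ± 0.39), AW112010 (2.89 ± 0.28), Irf8 (2.73 ± 0.47) and Ifi27l2a (2.53 ± 0.48). Ifitm1 went from 0 to 59 UMIs, at least 11.1-fold higher, and was over 10-fold higher in another class. Falls were in Ldlrad4 (-2.07 ± 0.48) and in epidermal genes over 10-fold higher in another class: Krt14 (-1.88 ± 0.23), Ly6d (-1.64 ± 0.22), Perp (-1.47 ± 0.29) and Krt10 (-1.46 ± 0.23). Keratinocyte markers summed to 3182 CPM in control and 1186 CPM in OVA-sensitized lymphoid cells. Il13 gave 2.21 ± 0.56 (adjusted p = 0.0616) and Il17a 2.38 ± 0.91 (adjusted p = 0.337). Il4 (0 and 6 UMIs), Il5 (2 and 68), Il22 (1 and 85), Ifng (1 and 129) and Foxp3 (5 and 28) did not pass the filter on low counts, those of Il22 and Ifng after OVA lying in 5 and 7 cells. In all lymphoid cells 20 genes rose and 16 fell of 2738 tested, 36 of them without overlap between groups, as were 15.6% of all tested genes (10% by chance).

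Regulatory T cell genes rose, with 1 of 7 up and 0 down (2 and 0 adjusted over the list alone, adjusted p = 0.0113, or 0.23 with an estimated correlation), a call lost without OVA-sensitized library 1 (adjusted p = 0.0604). Cell cycle genes rose as a list, with 0 of 6 up and 0 down (2 and 0 adjusted over the list alone, adjusted p = 0.0111, or 0.304 with an estimated correlation). The list call was lost without OVA-sensitized library 3 (adjusted p = 0.0572) or control library 3 (0.124). Other lists had too few tested members for a list test. Cytotoxic genes had 2 of 4 up and 0 down (3 and 0 adjusted over the list alone). Type 2 genes had 0 of 3 up and 0 down (1 and 0 adjusted over the list alone). The IL-17 and IL-22 axis had 0 of 3 up and 0 down (the same adjusted over the list alone). Dissociation genes had 0 of 19 up and 0 down (the same adjusted over the list alone, adjusted p = 0.921). The class holds few cells, and the CD4 T, regulatory T and NK shares within it rose. Under the same mix of second-level clusters, with 1284 genes tested, 3 passed, 2 of them among the 36, and 2 of 6 named calls were kept (Krt14 and Ly6d), while 18 genes passed without control library 2. Named calls lost numbered 5 without control library 1 (adjusted p 0.0612 to 0.091), 5 without 2 (0.0593 to 0.297) and 2 without 3 (0.0606 to 0.13). Losses were 1 without OVA-sensitized library 1 (adjusted p 0.126), 2 without 2 (0.0654 to 0.0858) and 2 without 3 (0.0655 to 0.073). The genes were Irf8, Ifi27l2a, Ldlrad4, Perp, Krtdap and Krt2.

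In macrophage- and monocyte-like cells, Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484, minus strand), the arginase induced by IL-4 and IL-13, went from 0 to 132 UMIs, at least 27.5-fold higher (adjusted p = 1.22e-06). Ccl8 rose from 5433 ± 1037 to 13476 ± 2453 CPM (log2 1.31 ± 0.14, adjusted p = 1.22e-06). The MHC class II gene H2-Ab1 rose (1.36 ± 0.13, adjusted p = 2.65e-07). Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938, plus strand), which attracts neutrophils, fell from 5097 ± 829.5 to 1356 ± 364 CPM (-1.91 ± 0.16, adjusted p = 5.94e-08). Tnf, the inflammatory cytokine, fell (-2.03 ± 0.20, adjusted p = 5.76e-07). Rises in AW112010 (4.33 ± 0.40), Ly6c2 (4.25 ± 0.30), Ms4a4c (3.76 ± 0.40), Plac8 (3.53 ± 0.24) and Inhba (3.43 ± 0.38) came with the larger share of monocyte-like cells, whose leading genes include AW112010, Ly6c2 and Plac8. Ifi44 (1 and 60 UMIs) and Pgf (3 and 85) rose by ratios of 37.5 (counting interval 6.48 to 1510) and 17.7 (5.86 to 87.7). Further falls were Fabp3 (-2.44 ± 0.46), Tnfsf9 (-2.38 ± 0.34), Cd209f (-2.29 ± 0.59) and Cd209b (-1.94 ± 0.27), the last 2 being close paralogs. Here 196 genes rose and 191 fell of 4306 tested, 377 of them without overlap between groups, as were 25.7% of all tested genes (10% by chance).

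MHC class II and interferon-gamma induced genes rose, with 10 of 13 up and 0 down (11 and 1 adjusted over the list alone, adjusted p = 3.9e-08, or 0.0424 with an estimated correlation). Interferon-stimulated genes rose, with 5 of 11 up and 1 down (7 and 1 adjusted over the list alone, adjusted p = 0.000136, or 0.143 with an estimated correlation). Rises were Xaf1 (2.58 ± 0.58), Zbp1 (2.08 ± 0.35) and Irf7 (2.02 ± 0.31), Irf7 being a master factor of the interferon response. IL-4 and IL-13 response genes rose, with 5 of 13 up and 2 down (6 and 2 adjusted over the list alone, adjusted p = 0.0032, or 0.224 with an estimated correlation). Tgm2 (1.54 ± 0.28) rose beside Arg1 and Ccl8, but Retnla (-2.40 ± 0.62) and Ccl24 (-0.59 ± 0.15), also induced by IL-4, fell. Chil3 gave 4 and 44 UMIs and was not tested. Chemokine genes fell, with 2 of 16 up and 9 down (3 and 9 adjusted over the list alone, adjusted p = 0.00264, or 0.143 with an estimated correlation). Cxcl13 (-3.19 ± 0.76) and Ccl20 (-1.60 ± 0.38) fell, the latter over 10-fold higher in another class. Dissociation genes fell, with 0 of 22 up and 8 down (0 and 12 adjusted over the list alone, adjusted p = 7.69e-05, or 0.143 with an estimated correlation). Keratinocyte markers summed to 3117 CPM in the controls and 1801 CPM after OVA. In cells named macrophage at the second clustering 128 genes passed, 93 of them among the 387, and 9 of 17 named calls were kept, those of Retnla and Ccl24 not among them, and the IL-4 and IL-13 list did not pass (adjusted p = 0.318). The mix of second-level clusters differed: that led by Ccl2 and Plau held 97, 103 and 81 cells in controls and 39, 36 and 65 after OVA. Drawn at the same mix of these clusters (84 cells per library, 1930 genes tested) 20 genes passed, 17 of them among the 387, and 4 of 15 named calls were kept (Ccl8, Cxcl1, Cxcl2 and Tnf). The chemokine list still fell there (adjusted p = 0.0276), but the MHC class II, IL-4 and IL-13 and dissociation lists did not pass (medians 0.05, 0.16 and -0.07, adjusted p = 0.178, 0.0823 and 0.679). These changes of the class are not shown within its clusters. In DESeq2, Retnla and Cxcl13 were not called. Calls lost among named genes were 2 without control library 1 (adjusted p 0.0781 to 0.0969), 4 without 2 (0.0626 to 0.692) and 6 without 3 (0.0556 to 0.171). Losses were 2 without OVA-sensitized library 1 (adjusted p 0.0581 to 0.0613), 1 without 2 (0.0673) and 1 without 3 (0.0953). The genes were Qpct, Gbp2, Cd209f, Atf3, Retnla, Jun, Cxcl13 and Ccl24.

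In dendritic- and Langerhans-like cells, Il23a (ENSMUSG00000025383, chromosome 10, 128296139 to 128298752, minus strand), a subunit of the IL-23 that maintains IL-17 cells, fell from 54.3 ± 25.4 to 1.71 ± 1.86 CPM (log2 -4.79 ± 0.60, adjusted p = 0.000582). Cxcl2 fell from 2665 ± 381 to 481 ± 66.6 CPM (-2.47 ± 0.14, adjusted p = 2.17e-06). Irf7 (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481, minus strand) rose from 5.96 ± 3.37 to 77.1 ± 41.3 CPM (3.69 ± 0.63, adjusted p = 0.00318). Clec10a, a lectin of type 2 dendritic cells, rose too (1.88 ± 0.32, adjusted p = 0.00318). Plac8 and Ly6c2 rose (5.27 ± 0.50 and 3.18 ± 0.81), and Klk1 went from 0 to 123 UMIs, at least 19.3-fold higher. Rises on 1 to 3 control UMIs, with counting intervals, were Stfa2 (1 and 79 UMIs, ratio 37.2, interval 6.48 to 1490) and Tmem108 (2 and 81 UMIs, ratio 19, interval 5.11 to 160), Stfa2 having close paralogs. Falls were seen in Mucl1 (-3.00 ± 0.74), Tnfrsf9 (-2.75 ± 0.37), Sdcbp2 (-2.74 ± 0.49) and Hpgds (-2.56 ± 0.45), with adjusted p at most 0.0244, Hpgds being a top gene of the Langerhans-like cluster. Ccl17, Ccl22 and Ccr7, genes of migrating dendritic cells, gave -1.04 ± 0.34, -0.39 ± 0.35 and -0.30 ± 0.20 (adjusted p = 0.0798, 0.564 and 0.406). In this class 179 genes rose and 256 fell of 4816 tested, 433 of them without overlap between groups, as were 29.4% of all tested genes (10% by chance).

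Chemokine genes fell, with 0 of 15 up and 7 down (1 and 8 adjusted over the list alone, adjusted p = 3.47e-06, or 0.104 with an estimated correlation). Falls were Cxcl1 (-2.10 ± 0.24), Ccl5 (-1.80 ± 0.45) and Ccl7 (-1.38 ± 0.17), Cxcl1 and Ccl7 being over 10-fold higher in another class. Dissociation genes fell, with 0 of 22 up and 7 down (0 and 12 adjusted over the list alone, adjusted p = 8.89e-05, or 0.104 with an estimated correlation). Interferon-stimulated genes rose, with 3 of 7 up and 0 down (5 and 1 adjusted over the list alone, adjusted p = 0.00496, or 0.255 with an estimated correlation). Bst2 (1.16 ± 0.26) was among them. MHC class II and interferon-gamma induced genes had 2 of 13 up and 3 down (3 and 4 adjusted over the list alone, adjusted p = 0.818). Cd74 fell (-0.56 ± 0.07), and the median was -0.07, the mean 0.05 and the test pointed down. IL-4 and IL-13 response genes had 1 of 10 up and 0 down (1 and 1 adjusted over the list alone, adjusted p = 0.529). The Langerhans-like cluster held 23.0% of the class in controls and 4.62% after OVA, and the cluster led by Naaa and H2-Aa 12.9% and 27.3%. An unnamed myeloid cluster led by Klk1, Spib, Ccr9 and Siglech held 0 cells in controls and 24 after OVA. With the same mix of second-level clusters, which leaves it out, 23 genes passed, 22 of them among the 435, and 4 of 18 named calls were kept (Plac8, Clec10a, Cxcl1 and Cd74), and Irf7, Klk1 and the interferon-stimulated list were not tested. Given the same mix of first clusters 51 genes passed, 49 of them among the 435, with 12 of 21 named calls kept, and the count was 214 without control library 2 and 263 without OVA-sensitized library 1. Leaving out 1 library ended named calls, namely 2 without control library 1 (adjusted p 0.0596 to 0.113), 5 without 2 (0.0706 to 0.182) and 7 without 3 (0.0509 to 0.145). Losses were 1 without OVA-sensitized library 1 (adjusted p 0.0885) and 1 without 3 (0.0511). The genes included Fosb, Ly6c2, Ccl5, Bst2, Gcsam and Mucl1.

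In vascular endothelial-like cells, Nts (ENSMUSG00000019890, chromosome 10, 102481756 to 102490486, minus strand) rose from 3.73 ± 3.64 to 115 ± 57.3 CPM (log2 4.94 ± 0.54, adjusted p = 0.00012). It encodes neurotensin and is a top gene of the lymphatic cluster, whose RNA was not tested as a source. Car4 rose from 21.6 ± 2.2 to 274 ± 64.9 CPM (3.66 ± 0.20, adjusted p = 2.29e-07). Vcam1, an adhesion molecule for leukocytes, rose (1.03 ± 0.19, adjusted p = 0.00651). Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731, plus strand), an antiviral gene induced by interferon, fell from 33.8 ± 4.87 to 11.8 ± 2.74 CPM (-1.50 ± 0.24, adjusted p = 0.00271), with its near-identical paralog Ifit3b (-1.41 ± 0.32). AA467197 (2.76 ± 0.41) rose too, and large falls were in epidermal genes over 10-fold higher in another class, Anxa8 (-2.65 ± 0.46) and Krtdap (-2.13 ± 0.20). Keratinocyte markers summed to 2095 CPM in the controls and 682 CPM after OVA. Here 96 genes rose and 123 fell of 7692 tested, 219 of them without overlap between groups, as were 20% of all tested genes (10% by chance).

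Interferon-stimulated genes fell, with 0 of 21 up and 10 down (0 and 14 adjusted over the list alone, adjusted p = 1.45e-13, or 0.0259 with an estimated correlation). Ifi44 (-1.25 ± 0.22) and Usp18 (-1.20 ± 0.15) were among them. Endothelial adhesion genes rose, with 2 of 19 up and 0 down (5 and 0 adjusted over the list alone, adjusted p = 0.0081, or 0.303 with an estimated correlation). The call was lost without OVA-sensitized library 1 (adjusted p = 0.051) or control library 2 (0.0651). Vwf (0.44 ± 0.10) rose beside Vcam1. Sele and Selp, selectins that slow leukocytes in venules, gave 0.53 ± 0.14 and 0.28 ± 0.11 (adjusted p = 0.0592 and 0.222). Dissociation genes fell, with 0 of 23 up and 5 down (1 and 13 adjusted over the list alone, adjusted p = 1.88e-06, or 0.269 with an estimated correlation). The cluster led by Selp and Ackr1 held 27.7% of the class in controls and 45.3% after OVA, the cluster led by Gpihbp1 and Flt1 72.3% and 54.7%. With the same mix of clusters the calls of Vcam1 and Vwf were lost and Sele and Selp gave -0.04 and -0.26, as was the call of the adhesion list (median 0.04, adjusted p = 0.931), while 14 of 18 named calls were kept. The count was 140 and 145 without control libraries 1 and 3. Of the named calls, those lost were 2 without control library 1 (adjusted p 0.0664 to 0.146), 2 without 2 (0.0894 to 0.12) and 2 without 3 (0.0753 to 0.113). Losses were 3 without OVA-sensitized library 1 (adjusted p 0.0661 to 0.122) and 2 without 3 (0.0501 to 0.103). The genes were Vwf, Ifit3b and Egr1.

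**Figure D2:**
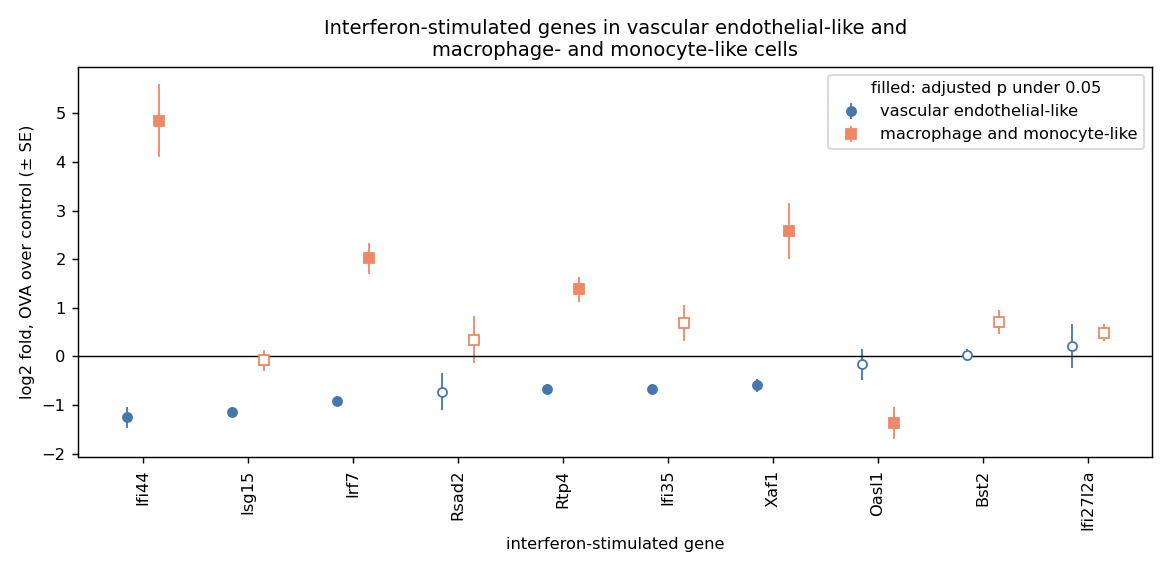
Log2 fold of OVA-sensitized over control ± SE for each interferon-stimulated gene tested in both vascular endothelial-like and macrophage- and monocyte-like cells, with filled points for adjusted p under 0.05. Of these 10 genes, 4 (Irf7, Ifi44, Rtp4 and Xaf1) fell in the former and rose in the latter.

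Among smaller classes, Il33 (ENSMUSG00000024810, chromosome 19, 29925114 to 29960718, plus strand) rose from 12.9 ± 11.2 to 171 ± 12.9 CPM in pericyte- and smooth muscle-like cells (log2 3.79 ± 0.31, adjusted p = 1.21e-07). Cst6 (-2.41 ± 0.32) and Krt17 (-2.37 ± 0.29), both over 10-fold higher in another class, fell. Keratinocyte markers summed to 2417 and 642 CPM. Dissociation genes fell, with 0 of 23 up and 7 down (1 and 9 adjusted over the list alone, adjusted p = 0.00232, or 0.362 with an estimated correlation). In this class 84 genes rose and 88 fell of 5013 tested, 171 of them without overlap between groups, as were 20.6% of all tested genes (10% by chance). The count was 91 without control library 2. Named calls lost were 2 without control library 1 (adjusted p 0.0503 to 0.123), 1 without 2 (0.123) and 3 without 3 (0.143 to 0.295). Losses were 1 without OVA-sensitized library 1 (adjusted p 0.0767), 2 without 2 (0.0643 to 0.112) and 2 without 3 (0.0595 to 0.1). The genes were Hspa1a, Ier2 and Atf3.

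In lymphatic endothelial-like cells the mitosis genes Ube2c (3.19 ± 0.57) and Birc5 (3.14 ± 0.56) rose, as did Cd74 (3.56 ± 0.51) and H2-Ab1 (3.05 ± 0.37), both over 10-fold higher in another class. Falls were in Serpinb5 (-2.74 ± 0.46) and Coch (-2.51 ± 0.60), also over 10-fold higher elsewhere, beside keratinocyte markers at 2043 and 714 CPM. Dissociation genes fell, with 0 of 23 up and 3 down (0 and 8 adjusted over the list alone, adjusted p = 2.85e-06, or 0.28 with an estimated correlation). DESeq2 did not call Ube2c, Birc5 or Coch. Here 33 genes rose and 41 fell of 6190 tested, 74 of them without overlap between groups, as were 15.7% of all tested genes (10% by chance). The count was 30 and 32 without control libraries 1 and 3, and 36, 125 and 37 without OVA-sensitized libraries 1, 2 and 3. Named calls lost numbered 5 without control library 1 (adjusted p 0.0645 to 0.182), 2 without 2 (0.0724 to 0.351) and 6 without 3 (0.0503 to 0.193). Losses were 2 without OVA-sensitized library 1 (adjusted p 0.108 to 0.17) and 2 without 3 (0.055 to 0.278). The genes were Birc5, Coch, Krt1, Hspa1a, Atf3 and Ube2c.

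In sebocyte-like cells the P450 gene Cyp2g1 rose from 159 ± 11.4 to 483 ± 166 CPM (log2 1.60 ± 0.21, adjusted p = 0.00779). Serpinb2 (-2.73 ± 0.38) and Sox4 (-1.72 ± 0.35), over 10-fold higher in another class, fell. Dissociation genes fell as a list, with 0 of 23 up and 0 down (0 and 6 adjusted over the list alone, adjusted p = 0.01, or 0.415 with an estimated correlation). In this class 18 genes rose and 11 fell of 6054 tested, 29 of them without overlap between groups, as were 18.7% of all tested genes (10% by chance). DESeq2 called 42 up and 15 down (73.7% up, against 62.1% in edgeR). The count was 4, 12 and 6 without control libraries 1, 2 and 3, and 58 and 66 without OVA-sensitized libraries 2 and 3. For the named genes, losses were 6 without control library 1 (adjusted p 0.0663 to 0.135), 5 without 2 (0.126 to 0.154) and 6 without 3 (0.0635 to 0.167). Losses were 4 without OVA-sensitized library 1 (adjusted p 0.0595 to 0.129), 1 without 2 (0.0608) and 3 without 3 (0.0583 to 0.0956). The genes were Gjb2, Pctp, Prss22, Sox4, Krtdap and Dusp6.

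In Schwann-like cells Krtdap (-2.04 ± 0.33), Calm4 (-1.89 ± 0.25), Krt10 (-1.74 ± 0.22) and Krt2 (-1.69 ± 0.33) fell, all over 10-fold higher in another class, beside keratinocyte markers at 4340 and 2646 CPM. By edgeR 0 genes rose and 6 fell of 3049 tested, with 216 genes at an unadjusted p under 0.05, and DESeq2 called 0 up and 4 down. Of the 6 genes none overlapped between groups, as for 12.8% of tested genes (10% by chance). On the same mix of clusters 0 genes passed in edgeR, with 106 at an unadjusted p under 0.05, and the count was 3, 2, 3, 3 and 19 without control libraries 1 and 2 and OVA-sensitized libraries 1, 2 and 3. Named calls lost were 1 without control library 1 (adjusted p 0.102) and 2 without 2 (0.11 to 0.332). Losses were 2 without OVA-sensitized library 1 (adjusted p 0.078 to 0.172) and 2 without 2 (0.0794 to 0.15). The genes were Krt2 and Krtdap. In hair matrix and shaft cells Krt2, over 10-fold higher in another class, was the only gene past the threshold (-2.11 ± 0.24, adjusted p = 0.0149) of 7372 tested, with 458 at an unadjusted p under 0.05 and 0 up and 4 down in DESeq2. It was lost without control library 1 (adjusted p = 0.0579) or 2 (0.11) or OVA-sensitized library 1 (0.501), where the counts were 0, 2 and 0, and the counts without OVA-sensitized libraries 2 and 3 were 6 and 2. Dissociation genes had 0 of 22 up and 0 down (the same adjusted over the list alone, adjusted p = 0.509) in Schwann-like cells. In hair cells they had 0 of 23 up and 0 down (the same adjusted over the list alone, adjusted p = 0.922), with a median of 0.0579, a mean of -0.00427 and a test pointing down.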

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

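The tests of handling, of free RNA moving the interferon list alike, of fibroblast-like cells without those richest in marker UMIs and of the same mix of clusters at both levels were chosen only after the results were seen, as was the use of the spread.

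Gene lists moved differently in different cell classes in 18 of 22 comparisons, each tested as the difference of log2 folds within libraries with a preset correlation, and with an estimated correlation none held (lowest adjusted p = 0.0684). None was tested with the same mix of clusters. Values are median differences in log2 fold over shared genes. For interferon-stimulated genes they were -1.01, -1.28 and 0.686 for keratinocyte-like against macrophage-like, dendritic and vascular cells. For fibroblast-like against the same cells they were -1.16, -0.774 and 0.518. For macrophage-like and dendritic against vascular cells they were 1.21 and 1.07 (adjusted p at most 0.00425 in all). For chemokines they were 0.391, 1.5 and 1.45 for keratinocyte-like against fibroblast-like, macrophage-like and dendritic cells. For fibroblast-like against macrophage-like and dendritic cells they were 1.23 and 1.42, and for macrophage-like against dendritic cells 0.553 (adjusted p at most 0.0348 in all). For cell cycle genes they were -1.14 for keratinocyte-like against fibroblast-like cells and -0.778 for keratinocyte-like against lymphoid cells (adjusted p at most 0.00411). The IL-4 and IL-13 response gave -0.437 for fibroblast-like against macrophage-like cells (adjusted p = 0.0385), and MHC class II genes 1.08 for macrophage-like against dendritic cells (adjusted p = 6.73e-05).

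Keratinocyte genes were lower after OVA in other cell classes, with 20 of 23 markers down in fibroblast-like and 14 of 19 in vascular cells, but only 1 of 16 in dendritic cells. Lower depth of the control cells as the whole account is argued against, since marker UMIs per fibroblast-like cell changed by -48.5% with no overlap between groups. Across markers, levels in 5 other classes of controls followed those in keratinocyte-like cells (lowest Pearson r 0.895 over genes, which are not independent replicates; 0.89 in lymphatic and 0.893 in Schwann-like cells, which the test did not include). This is in line with free keratinocyte RNA in the droplets, which may have been lower where keratinocytes were fewer. Droplets with a keratinocyte and another cell as the whole cause are argued against, since the 5% of control fibroblast-like cells with most marker UMIs held 29.1% of them (libraries 18.1 to 35.1%, bound 30%), 99.1% held at least 1, and without the richest 5% of each library marker UMIs per cell changed by -49.8%, again with no overlap. A change in low expression by these cells themselves stays open and was not tested.

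Interferon-stimulated genes fell in vascular cells and rose in macrophage- and monocyte-like cells. A different mix of vascular clusters as the whole cause is argued against, since the median with the same mix was -0.71, and so is a single library, since the largest adjusted p without 1 library was 5.96e-10. Free RNA moving the list alike everywhere was not put to a separate test, since the classes were picked for their opposite moves. The difference between them had adjusted p = 1.06e-06 (0.0684 with an estimated correlation), and 4 of 10 shared genes were called in opposite directions. Both restate the pattern. For the rise, a different mix of second-level clusters cannot be told apart, since only 4 members were tested with the same mix (median -0.354) and monocyte-like cells, with Irf7 among their top genes, rose in share. A candidate explanation that stays open is a different response of these cells to OVA sensitization.

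Dissociation genes fell in macrophage- and monocyte-like cells, with a median log2 fold of -0.48, and also in fibroblast-like, dendritic, vascular, lymphatic, pericyte-like and sebocyte-like cells (medians -0.383 to -0.214), though with an estimated correlation none of these 7 passed (adjusted p from 0.091 to 0.415). A handling difference acting alike on every class is argued against by the median of -0.00381 in keratinocyte-like cells, while one acting on the 7 classes that fell stays open. With the same mix of second-level clusters the median shrank from -0.483 ± 0.0799 to -0.0737 ± 0.0687 (SE over genes, adjusted p = 0.679). This cannot decide on the mix as the whole cause, since Egr1, Jun, Fos and Atf3, genes of the list, led a matched cluster. Monocyte-like cells alone cannot be told apart as the cause, since the median in cells named macrophage was -0.245, at its bound within the spread. A change in these cells after OVA also stays open. In fibroblast-like, vascular and dendritic cells the same mix of clusters left medians of -0.157 ± 0.0544, -0.265 ± 0.0613 and -0.262 ± 0.0913. These argue against the mix of clusters as the whole cause there.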

How the results depend on the processing

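The settings with the same mix of clusters, with the same mix of second-level clusters and with cells named at the second clustering were chosen only after the results were seen.

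Of the genes in the rule's set past the threshold, DESeq2 kept 236 of 270, its size factors in edgeR 286 of 287, no filter 287 of 287, stricter cells 261 of 281, doublets kept 248 of 287, equal numbers of cells 156 of 186, the same mix of clusters 64 of 109, that of second-level clusters 10 of 39 and the block 283 of 287. With 1 library left out, 230 of 287 (control library 3) to 263 of 284 (OVA-sensitized library 2) were kept. Of 35 described lists past the threshold, the estimated correlation kept 2 and the block 34. The numbers in the titles gave little sign of pairs (paired correlations of library deviations in all cells 0.0687, 0.0487 and -0.0561), so the blocked values stand here. Depth limits lymphoid cells most, with 98648 UMIs in the smallest library.

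The numbers of genes changed, 6717 (all cells), 378 (keratinocyte-like), 985 (fibroblast-like), 387 (macrophage-like), 435 (dendritic), 219 (vascular), 74 (lymphatic), 172 (pericyte-like), 29 (sebocyte-like), 6 (Schwann-like), 1 (hair) and 36 (lymphoid), moved by over 1.5 times in some settings, which follow, but not in all cells, and the values without 1 library are given for every class. With DESeq2 they were 251 (dendritic), 464 (fibroblast-like), 4 (hair), 40 (lymphatic), 21 (lymphoid), 178 (macrophage-like), 93 (pericyte-like), 57 (sebocyte-like) and 125 (vascular). Without a filter on low counts, which tests more genes, they were 23 (Schwann-like), 655 (dendritic), 1556 (fibroblast-like), 125 (hair), 711 (keratinocyte-like), 173 (lymphatic), 112 (lymphoid), 214 (sebocyte-like) and 419 (vascular). With doublets kept they were 1 (Schwann-like), 733 (dendritic), 3 (hair), 34 (lymphatic), 105 (pericyte-like) and 18 (sebocyte-like). With equal numbers of cells they were 3 (Schwann-like), 267 (dendritic) and 5 (sebocyte-like). With the same mix of clusters they were 0 (Schwann-like), 51 (dendritic), 377 (fibroblast-like) and 39 (keratinocyte-like). With the same mix of second-level clusters they were 23 (dendritic), 3 (lymphoid) and 20 (macrophage-like). Without genes over 10-fold higher in another class, which tests fewer, they were 1 (Schwann-like), 0 (hair), 251 (keratinocyte-like) and 32 (lymphatic). With the replicate number as a block they were 5 (hair), 120 (lymphatic), 70 (lymphoid) and 99 (sebocyte-like). With stricter cells they were 0 (hair) and 18 (sebocyte-like). With clusters at resolution 0.5 they were 0 (hair). In cells named at the second clustering they were 128 (macrophage-like). With 1 library left out they ran from 5203 to 6009 (all cells), 84 to 350 (keratinocyte-like), 615 to 840 (fibroblast-like), 258 to 346 (macrophage-like), 214 to 371 (dendritic), 140 to 256 (vascular), 30 to 125 (lymphatic), 91 to 198 (pericyte-like), 4 to 66 (sebocyte-like), 2 to 19 (Schwann-like), 0 to 6 (hair) and 18 to 39 (lymphoid). The cause was not tested, except that tests on 5 libraries, fewer cells or fewer genes hold less information.

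With an estimated correlation the lists past the threshold numbered 0 (all cells), 0 (Schwann-like), 0 (dendritic), 0 (fibroblast-like), 0 (hair), 0 (keratinocyte-like), 1 (lymphatic), 0 (lymphoid), 1 (macrophage-like), 1 (pericyte-like), 0 (sebocyte-like) and 2 (vascular). With 1 library left out they ran from 11 to 13 (all cells), 4 to 8 (keratinocyte-like), 9 to 10 (fibroblast-like), 9 to 9 (macrophage-like), 5 to 8 (dendritic), 6 to 8 (vascular), 4 to 6 (lymphatic), 5 to 6 (pericyte-like), 3 to 6 (sebocyte-like), 3 to 5 (Schwann-like), 0 to 5 (hair) and 1 to 3 (lymphoid).

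Shares in percentage points reversed for lymphatic cells (-0.58, without epithelial cells), lymphoid cells (-0.209, among leukocytes), macrophage-like cells (-7.56, among leukocytes) and pericyte-like cells (-0.457, without epithelial cells). Among leukocytes log2 abundance was 0.085 (dendritic, adjusted p = 0.554), -0.029 (lymphoid, adjusted p = 0.84) and -0.22 (macrophage-like, adjusted p = 0.0158). Without epithelial cells log2 abundance was 0.076 (fibroblast-like, adjusted p = 0.138), -0.19 (lymphatic, adjusted p = 0.159), -0.13 (pericyte-like, adjusted p = 0.322) and 0.018 (vascular, adjusted p = 0.836). With TMM factors on cell numbers log2 abundance was 0.03 (fibroblast-like, adjusted p = 0.625), -0.23 (lymphatic, adjusted p = 0.0799), -0.17 (pericyte-like, adjusted p = 0.177) and -0.029 (vascular, adjusted p = 0.745). With doublets kept log2 abundance was 0.23 (lymphatic, adjusted p = 0.0347) and -0.37 (melanocyte-like, adjusted p = 0.0846). With replicates as a block log2 abundance was -0.58 (melanocyte-like, adjusted p = 0.0541). Without 1 library log2 abundance ran from -0.52 to -0.31 (hair), 0.15 to 0.28 (lymphatic), -0.87 to -0.20 (melanocyte-like), 0.23 to 0.35 (pericyte-like) and -0.55 to -0.31 (sebocyte-like), and within parent classes from 0.88 to 1.30 (conventional CD4 T), -0.88 to -0.59 (dermal gamma-delta T), 0.98 to 1.5 (NK), 0.68 to 1.18 (regulatory T) and 0.11 to 1.32 (migratory DC). At the lower second resolution conventional dendritic-like cells gave -0.077. Among lymphoid cells, the difference in the share with Il4 or Il13 ran from 0.248 to 4.12 points.

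Lists that had not passed turned direction without 1 library, with adjusted p over those fits of 0.195 to 0.963 (cell cycle in keratinocyte-like cells), 0.0719 to 0.868 (dissociation stress in Schwann-like cells), 0.513 to 0.966 (dissociation stress in hair cells), 0.3 to 0.925 (dissociation stress in keratinocyte-like cells), 0.318 to 0.938 (dissociation stress in lymphoid cells), 0.648 to 0.988 (alarmins in all cells), 0.628 to 0.981 (glycolysis in all cells), 0.578 to 0.985 (MHC class II in dendritic cells), 0.466 to 0.98 (interferon-stimulated in fibroblast-like cells) and 0.0754 to 0.988 (skeletal muscle RNA in all cells summed). Among genes that had not passed, log2 folds turned for Tsix in all cells (-0.15 to 0.36), Il33 in all cells (-0.06 to 0.04), Flg in keratinocyte-like cells (-0.47 to 0.45), Lor in keratinocyte-like cells (-0.55 to 0.01), S100a9 in keratinocyte-like cells (-0.34 to 0.57) and Ccl22 in dendritic cells (-0.73 to 0.30). With all barcodes Tsix in all cells gave -0.02 and Il33 in all cells gave 0.00. With doublets kept Alas2 in all cells gave 0.47 and Ccr7 in dendritic cells gave 0.02. With clusters at resolution 0.5 S100a9 in keratinocyte-like cells gave -0.39. With the same mix of clusters Lor in keratinocyte-like cells gave 0.20, Sele in vascular cells gave -0.04 and Selp in vascular cells gave -0.26. With the same mix of second-level clusters H2-DMb1 in macrophage-like cells gave -0.02 and Fosb in dendritic cells gave 0.11. These 2 and Alas2 in all cells were the called genes to turn. The cause was not tested.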

Other observations

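The tests of class makeup and of other splits for gene counts were chosen only after the results were seen, as were the genes and lists named here outside the rule.

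In pericyte- and smooth muscle-like cells, genes of extracellular matrix and remodelling rose, with 13 of 22 up and 0 down (15 and 0 adjusted over the list alone, adjusted p = 1.99e-11, or 0.0247 with an estimated correlation). In fibroblast-like cells, cell cycle genes rose, with 18 of 25 up (20 adjusted over the list alone, adjusted p = 1.16e-16, or 0.091 with an estimated correlation). In macrophage- and monocyte-like cells, glycolysis and hypoxia genes rose, with 7 of 14 up and 0 down (9 and 0 adjusted over the list alone, adjusted p = 0.000136, or 0.143 with an estimated correlation), but did not pass in cells named macrophage at the second clustering (adjusted p = 0.318) or with the same mix of second-level clusters (0.327). In lymphatic endothelial-like cells, MHC class II and interferon-gamma induced genes, of which Cd74 and H2-Ab1 were over 10-fold higher in another class, rose, with 6 of 14 up and 1 down (7 and 1 adjusted over the list alone, adjusted p = 2.27e-05, or 0.28 with an estimated correlation).

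The class counts of the 3 libraries of a group differed with a chi-square p of 0.863 in controls and 0.00593 after OVA, over 13 and 15 classes. Whether libraries of a group came from 1 suspension cannot be told apart from separate mice, since the smaller p lies between the bounds set for either.

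The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share of splits under 0.05. The real split and the highest other split called 6717 and 0 genes in all cells, 378 and 2 in keratinocyte-like, 985 and 0 in fibroblast-like, 36 and 2 in lymphoid, 387 and 0 in macrophage- and monocyte-like, 435 and 0 in dendritic, 219 and 0 in vascular, 74 and 2 in lymphatic, 172 and 1 in pericyte-like, 29 and 3 in sebocyte-like, 6 and 0 in Schwann-like and 1 and 1 in hair cells. For cell numbers they called 13 and 0 classes, 4 and 0 lymphoid and 6 and 0 myeloid subclasses. The number of splits with as many calls as the real one was 1 in each of these, and 2 in hair cells.

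Blood cell RNA gave 17.2 to 187 CPM per library, skeletal muscle RNA 18.3 to 116 and dissociation genes 18370 to 19090 in controls and 16440 to 18000 after OVA. Y-linked genes gave 0 or 1 UMI in every library, beside Xist in all.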
